A study of Homo sapiens with 6 samples.

How the data were processed

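Per the labels, the series holds 6 arrays of LNCaP cells exposed for 6 h to 20 µM gedunin (3 arrays) or to DMSO (3 arrays). The labels number the arrays of a group as biological replicates. The array labelled DMSO 3 did not read like LNCaP cells, as described below. The deposited table gives 1 intensity per array for each of 22215 probe sets, made with RMA per the submitters' processing notes, which give no version. RMA corrects background, applies quantile normalization across arrays and summarises the probes of each probe set. Which arrays were processed together is not stated, and the table holds no detection calls. The values were on a linear scale, with a lowest intensity of 11.0 and no negative values, so log2 was taken, as the design had foreseen. No raw array files were used.

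Probe sets were joined to genes with the annotation of 2016 supplied for this platform. Of the probe sets, 19724 named exactly 1 gene symbol, 568 named several and 1923 were not listed, and the last 2 kinds were tested but given no gene name. Entrez identifiers of 19707 probe sets matched the RefSeq gene table, and the match changed 0 symbols. A gene was represented by the probe set with the highest mean over all 6 arrays among those naming that gene alone, which gave 12165 genes, 4505 of them with at least 2 probe sets. Sex-linked marker genes were left out of all tables of values.

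Gedunin was compared with DMSO by limma (version 3.58.1, R 4.3.3), with lmFit and eBayes without trend on log2 intensity and no filter on dim probe sets. Adjusted p-values are Benjamini-Hochberg values over all probe sets, the threshold was 0.05, and a gene took the adjusted p of its probe set. Errors are moderated standard errors. The array labelled DMSO 3 differed from the other 5 in the genes it expressed. The fixed design with all 6 arrays was kept, and each count, list and named gene was computed again without that array (3 against 2 arrays). Leaving out each array in turn was planned, but giving this fit throughout was chosen after seeing the data.

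In all, 28 gene lists were fixed before the values were seen, covering stress responses, androgen response, metabolism, growth, proteostasis, chromatin, signalling and cell types. Each was tested by limma's camera at gene level with the preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, and was adjusted over the 28 lists. Estimating the correlation also lowers the degrees of freedom of camera's test, so a call lost with it need not mean correlated members. Members past the threshold were counted by direction, over all probe sets and adjusted over the list alone. ATF3, DDC, FKBP5, FOLH1, NDRG1, NQO1, SLC7A11, SPDEF and SQSTM1 belong to more than 1 list. To describe the array labelled DMSO 3, 5 further marker lists (myeloid, B lymphoid, T lymphoid, erythroid, epithelial) were written before they were tested but after that array was seen to stand apart. For each list the genes at least 8-fold above or below the mean of the other 5 arrays were counted.

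Named genes were chosen by a rule fixed beforehand. Among genes past the threshold with all gedunin arrays on the same side of all DMSO arrays, the 12 largest rises and the 12 largest falls were named. For each list past camera or with 3 or more called members, up to 4 called members with the largest change were named. KLK3, KLK2, TMPRSS2, FKBP5, HSPA1A, HSPA8, DNAJB1, HSPH1, HSP90AA1, HSP90AB1, BAG3, HSPA5, DDIT3, ATF3, HMOX1, MYC, CDKN1A and HMGCS1 were named whatever their result, and 2 further genes of this rule are not analysed here. The rule was applied again without the array labelled DMSO 3. It named 104 genes, of which 52 came only from the fit without that array, and 9 of those had the opposite sign with all 6 arrays. Further members of lists are named as exceptions, chosen after their values were seen, where a list had few called members or members that did not move. Of the called named genes, 49 had other probe sets. For 38 of them another probe set passed in the same direction, for 11 none did, and for 0 did one pass in the opposite direction.

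The alternatives planned were a filter on dim probe sets, centring on the median, a second quantile normalization, a replicate block, eBayes with trend and robust, array weights, leaving out each array, a threshold of 0.01, dropping probe sets with the suffixes _x_at and _s_at, the mean of all probe sets of a gene, and log2 of the value plus 16. Centring on control probe sets and the comparison of RNA quality were not run because the table holds 0 AFFX control probe sets, and centring on GAPDH and ACTB was used in place of the former. The code was tested on simulated data with 50 changed probe sets of each size. With 6 LNCaP-like arrays it recovered 52, 92, 100 and 100 percent of log2 changes of 0.5, 1, 2 and 4, with 3 false calls. With the array labelled DMSO 3 in place as deposited it recovered 0, 34, 70 and 86 percent, with 0 false calls, and with 5 arrays 32, 88, 100 and 100 percent, with 6 false calls.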

Results

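LNCaP is a human prostate cancer cell line that responds to androgen and makes prostate-specific antigen. Gedunin is a limonoid natural product of neem and related trees. The cells were exposed to 20 µM gedunin or to DMSO, its solvent, for 6 h, and the RNA of each culture was hybridised to an Affymetrix array. By the labels there were 3 arrays of gedunin-treated and 3 of DMSO-treated cells, numbered as biological replicates. Each array gave an intensity for 22215 probe sets, of which 19724 named exactly 1 gene, for 12165 genes in all. Lower quartiles of intensity lay between 19.4 and 20.7 and upper quartiles between 128 and 146. The number of arrays limits the precision, and p-values measure the spread between these arrays. Known context for the study is that gedunin was examined as a compound that lowers androgen signalling and was compared with HSP90 inhibitors. The comparison of treated with control cells asks which genes respond within hours of exposure.

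The array labelled DMSO 3 lacked the signal of prostate genes and carried strong signal from leukocyte genes. FOLH1, which encodes prostate-specific membrane antigen, read 25.03 on it against 7183 on DMSO 1 and 7626 on DMSO 2. KLK3, which encodes prostate-specific antigen, read 24.5 against 2093 and 1810, and the luminal keratin KRT18 read 23.9 against 2505 and 2517. CD74, the class II invariant chain, read 4294 on that array and between 19.1 and 20.8 on the other 5. HLA-DRA, a class II antigen-presenting chain, read 4195 against 17.3 to 19.8, and the leukocyte common antigen PTPRC read 435 against 23.3 to 24.5. GAPDH read 10686 there and between 10124 and 10859 elsewhere. Of the 11 measured genes of the luminal prostate identity list, 7 lay at least 8-fold below the mean of the other 5 arrays, with a median log2 difference of -4.32. Of 10 measured leukocyte genes, 6 lay at least 8-fold above it, with a median of 3.61.

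**Figure D1:**
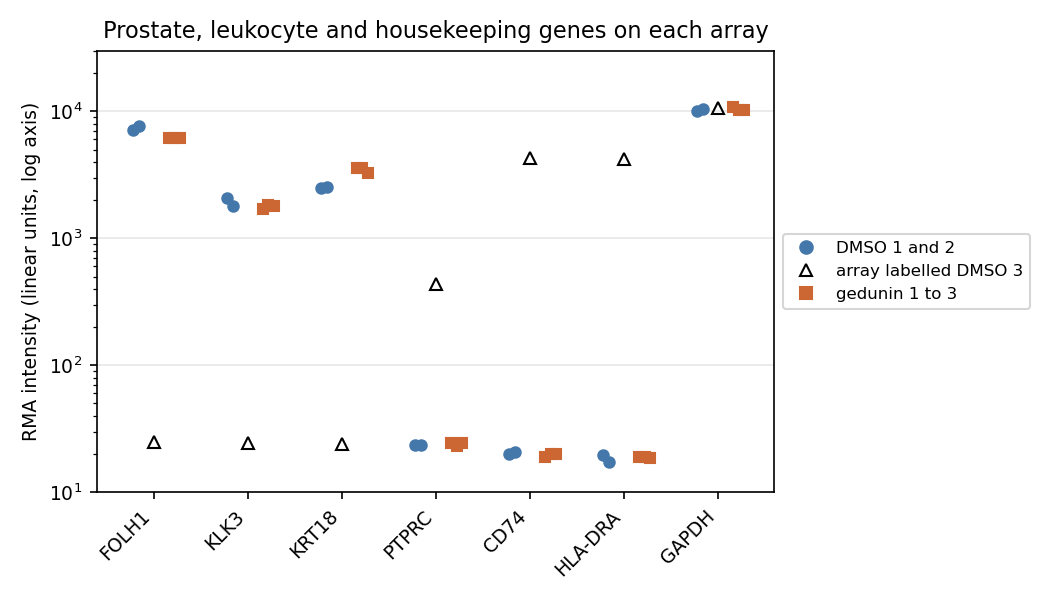
Intensity (linear units, logarithmic axis) of 3 prostate or luminal genes, 3 leukocyte genes and GAPDH on each array, with 1 symbol per array. On the array labelled DMSO 3, FOLH1, KLK3 and KRT18 lie near 25 while PTPRC, CD74 and HLA-DRA lie between 435 and 4294, and GAPDH lies among the other arrays.

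Across probe sets, which are not independent replicates, the Spearman correlation of this array with the other 5 was 0.812 to 0.819. It was 0.976 to 0.980 between the remaining arrays of the same group and 0.965 to 0.971 between gedunin arrays and DMSO 1 or 2. On the array labelled DMSO 3, 669 probe sets were at least 4-fold above every other array and 671 at least 4-fold below, while the count was 0 in both directions for each of the other 5. Counts and list tests are given for all 6 arrays, the design fixed beforehand (the 6-array fit), and again without the array labelled DMSO 3 (the 5-array fit, 3 against 2). Giving the latter throughout was decided after the values were seen. Some genes are given for 1 fit alone. Errors are limma's moderated standard errors of the log2 fold change, gedunin over DMSO, with n = 3 and 3 arrays, or 3 and 2 in the 5-array fit.

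In the 6-array fit, 204 of 12165 genes passed an adjusted p of 0.05, of which 161 were higher and 43 lower with gedunin. At least 2-fold changes were seen for 109 higher and 15 lower genes. HSPA6, a strictly stress-inducible HSP70, rose most, by a log2 fold change of 6.46 ± 0.13 (adjusted p = 3.29e-04), from a mean intensity of 24.3 on DMSO 1 and 2 to 2159. HMOX1, the heme-degrading enzyme heme oxygenase 1, rose by 5.66 ± 0.58 (adjusted p = 0.0190), DDIT3, the stress transcription factor CHOP, by 4.67 ± 0.30 (adjusted p = 0.00521), and ATF3, another stress-inducible transcription factor, by 4.59 ± 0.56 (adjusted p = 0.0326).

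The other 8 of the 12 largest rises in the 6-array fit were CHAC1 (4.55), AKR1C2 (4.52), DNAJB1 (4.15), AKR1C1 (4.10), MIR22HG (4.08), TRIB3 (3.84), DNAJB4 (3.67) and CRYAB (3.66). MIR22HG, the host transcript of microRNA 22, belonged to none of the fixed lists. The largest falls were smaller. ZC3HAV1, an antiviral zinc finger protein, fell by 1.64 ± 0.17 (adjusted p = 0.0190), and RRS1, a ribosome assembly factor, by 1.40 ± 0.08 (adjusted p = 0.00367). The next largest were the PI3-kinase catalytic subunit PIK3CD (-1.38), BYSL (-1.37), KNOP1 (-1.32), GEMIN4 (-1.31), SCO2 (-1.25), ABCE1 (-1.22), PSD4 (-1.19), PHF20 (-1.10), METTL13 (-1.10) and IMP3 (-1.10). All 3 gedunin arrays lay on the same side of all 3 DMSO arrays for each of these genes. On the probe sets of ZC3HAV1, PIK3CD and GEMIN4 other than the one used, none passed in the same direction in the 5-array fit, and the same holds for DNAJC7, PEG3, CYP1A2, IFIH1 and H2BC5 among the genes named below.

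Without the array labelled DMSO 3, 2138 genes passed, 1000 higher and 1138 lower, and all 204 genes of the 6-array fit were among them in the same direction. At least 2-fold changes numbered 224 higher and 72 lower genes, and 118 genes had them in both fits. PRR15L, an epithelial gene of little-known function, fell by 2.35 ± 0.09, the largest fall in this fit (adjusted p = 2.14e-07), although its 6-array value was -1.47 ± 0.75 (adjusted p = 0.545). Its mean intensity with gedunin was 30.4, below the array median, where RMA compresses folds. The same holds for CYP1A1 (28.6) and DNASE2B (25.5), named below. The 12 rises named above were HSPA6 6.47, HMOX1 6.30, DDIT3 4.33, ATF3 3.94, CHAC1 4.24, AKR1C2 4.36, DNAJB1 3.92, AKR1C1 3.78, MIR22HG 3.98, TRIB3 3.31, DNAJB4 3.29 and CRYAB 3.66 in this fit, and the falls RRS1 -1.37, PIK3CD -1.17, BYSL -1.20, KNOP1 -1.21, GEMIN4 -1.21, SCO2 -1.27, ABCE1 -1.12, PSD4 -1.32, PHF20 -1.26, METTL13 -1.04 and IMP3 -1.13, all called. NIBAN1, a stress-induced regulator of translation, rose by 3.52 ± 0.11 from a level below the array median on DMSO 1 and 2. The further large falls in this fit were C1orf116 (-2.01), CYP1A1 (-1.57), the peptide hormone gene RLN2 (-1.55), GUSBP14 (-1.52), ZC3HAV1 (-1.49), RAB4A (-1.49), the epithelial splicing regulator ESRP2 (-1.42), POLR1C (-1.41), DNASE2B (-1.41), TMEM168 (-1.40) and CYREN (-1.39).

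Over probe sets, limma called 312 of 22215 in the 6-array fit (252 higher, 60 lower) and 3396 in the 5-array fit (1638 higher, 1758 lower). At an unadjusted p of 0.05 the counts were 2634 and 6005. In the 5-array fit, centring each array on GAPDH and ACTB turned the split of probe sets into 1130 higher and 4139 lower, that of genes into 710 and 2562, and that of 2-fold genes into 164 and 119. ACTB itself read 12559 to 13255 with gedunin against 9921 and 10630 on DMSO 1 and 2, and this centring moved the median of all genes to -0.15. The direction of a small change thus depends on the reference chosen.

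Most heat shock response genes rose. In the 6-array fit, 18 of 26 measured members rose and 0 fell (24 adjusted over the list alone), with a median log2 fold change of 1.73. Without the array labelled DMSO 3, 25 rose and 0 fell (25 adjusted over the list alone), with a median of 1.68, and the member not called was HSF1, the transcription factor of this response (-0.060 ± 0.10). DNAJB1, the HSP40 partner of HSP70, rose by 4.15 ± 0.21 (adjusted p = 0.00360), and CRYAB, a small heat shock protein, by 3.66 ± 0.09 (adjusted p = 3.42e-04). The HSP110 gene HSPH1 rose by 2.89 ± 0.36 (adjusted p = 0.0334).

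HSP90AA1, the inducible cytosolic HSP90, rose by 1.06 ± 0.10 (adjusted p = 0.0145), and the constitutive chaperone HSPA8 by 0.80 ± 0.09 (adjusted p = 0.0221). Without the array labelled DMSO 3 the rises were 3.31 (HSPH1), 1.11 (HSP90AA1) and 0.75 (HSPA8). HSP90AB1 was called in the 5-array fit only, at 0.66 ± 0.09 (adjusted p = 6.76e-04), against 0.89 ± 0.21 (adjusted p = 0.157) with all 6 arrays. BAG3, an HSP70 cochaperone, had 4.42 ± 0.77 with all 6 arrays (adjusted p = 0.0787) and rose by 3.51 ± 0.09 without the array labelled DMSO 3 (adjusted p = 9.23e-09). HSPA1A was likewise called in the 5-array fit only, with 2.63 ± 1.05 with all 6 arrays (adjusted p = 0.419) and 3.86 ± 0.17 (adjusted p = 3.88e-07). Leaving out the array labelled DMSO 3 thus raised the fold of HSPA1A and lowered that of BAG3. HSPA1A and HSPA1B are near-identical copies, so their probe sets may read both. They did not move alike, however, as HSPA1B had 3.89 with all 6 arrays and 2.68 without the array labelled DMSO 3. The levels of HSPA6 and HSPA1A on DMSO 1 and 2 lay below the array median, where RMA compresses folds. On the array labelled DMSO 3, HSPA1A read 283, above it.

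The list passed the camera test in both fits (adjusted p = 2.35e-35 and 3.72e-38), and passed with an estimated correlation as well (adjusted p = 0.00399 and 0.0331). The list of HSP90 cochaperones, proteins that assist HSP90, left out those placed on the heat shock list. Among the latter, CHORDC1 rose by 1.92 in the 6-array fit (limma adjusted p = 0.00195). FKBP4 rose by 1.17 in the 5-array fit (adjusted p = 1.31e-05) but was not called with all 6 arrays (1.60, adjusted p = 0.152). Of the 14 measured genes of the cochaperone list, 2 rose in the 6-array fit, DNAJC7 (1.12 ± 0.16) and the p23 gene PTGES3 (0.88 ± 0.12), and 0 fell (2 and 0 adjusted over the list alone). The 5-array fit added BAG2 (1.38 ± 0.11) and ST13 (0.33 ± 0.09), so that 4 rose and 0 fell, also adjusted over the list alone. The median of this list was 0.10 in the 6-array fit (camera adjusted p = 0.0494; adjusted p = 0.579 with an estimated correlation) and -0.0096 in the 5-array fit (camera adjusted p = 0.312), where its mean was 0.18 and the camera direction up.

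**Figure D2:**
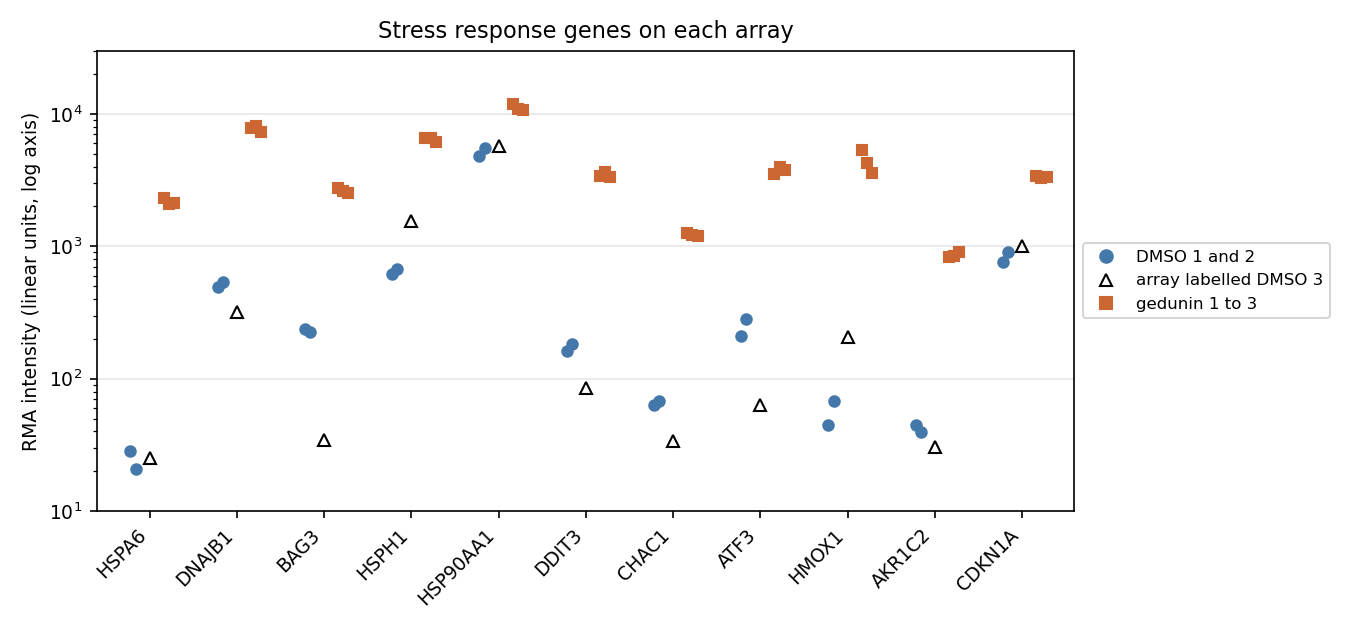
Intensity (linear units, logarithmic axis) of 11 stress response genes on each array, with 1 symbol per array. For HSPA6, DNAJB1, BAG3, DDIT3, CHAC1, ATF3, HMOX1 and AKR1C2 the 3 gedunin arrays lie more than 8-fold above every DMSO array, while HSP90AA1 and CDKN1A show smaller steps and the array labelled DMSO 3 lies apart from DMSO 1 and 2 for several genes, BAG3, ATF3, HMOX1, HSPH1, DDIT3 and CHAC1 among them.

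Genes of the ATF4 and amino acid response supply amino acids and charge tRNAs when translation is restrained. With all 6 arrays, 10 of 28 measured members rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 1.75. Without the array labelled DMSO 3, 26 rose and 0 fell (28 and 0 adjusted over the list alone), with a median of 1.31. CHAC1, a glutathione-degrading enzyme, rose by 4.55 ± 0.28 (adjusted p = 0.00486), and TRIB3, a pseudokinase that restrains ATF4, by 3.84 ± 0.46 (adjusted p = 0.0299). The list passed camera in both fits (adjusted p = 2.62e-24 and 9.42e-37). With an estimated correlation it did not pass with all 6 arrays (adjusted p = 0.149 with an estimated correlation) and passed without the array labelled DMSO 3 (adjusted p = 0.0459).

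The ER chaperone and unfolded protein response list rose in part. In the 6-array fit, 3 of 18 measured members rose, DNAJB9 (3.42 ± 0.44), HERPUD1 (2.39 ± 0.30) and XBP1 (1.10 ± 0.10), and 0 fell (7 and 0 adjusted over the list alone). DNAJB9 is an ER-resident HSP40, HERPUD1 serves ER-associated degradation and XBP1 is a transcription factor of the response. Their rises without the array labelled DMSO 3 were smaller, at 2.91 (DNAJB9), 2.05 (HERPUD1) and 1.04 (XBP1). In the 5-array fit, 8 rose and 0 fell (11 and 0 adjusted over the list alone), among them HSPA5, the main ER chaperone BiP (0.77 ± 0.11, adjusted p = 9.50e-04), which was not called with all 6 arrays (0.91 ± 0.16, adjusted p = 0.0756). The ER folding genes HSP90B1 (0.015 ± 0.09), CALR (-0.055 ± 0.09) and PDIA4 (-0.037 ± 0.11) were not called in either fit. Medians were 0.21 and 0.35, with camera adjusted p = 5.66e-05 and 7.15e-07. The calls were lost with an estimated correlation (adjusted p = 0.134 and 0.0767 with an estimated correlation). The estimates themselves, -0.048 and 0.012, were below or close to the preset 0.01.

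Genes of the NRF2 antioxidant response rose in part. The 6-array fit had 6 of 22 measured members higher and 0 lower (11 and 0 adjusted over the list alone), with a median of 2.01. The 5-array fit had 15 higher and 0 lower (16 and 0 adjusted over the list alone), with a median of 1.17. AKR1C2 rose by 4.52 ± 0.16 (adjusted p = 0.00129) and AKR1C1 by 4.10 ± 0.28 (adjusted p = 0.00644). They encode near-identical aldo-keto reductases, so their probe sets may share signal. GCLM, the regulatory subunit of the glutathione-synthesising ligase, rose by 2.62 ± 0.39 (adjusted p = 0.0480), and by 2.18 ± 0.09 without the array labelled DMSO 3. OSGIN1, an oxidative stress-induced growth inhibitor, rose by 2.59 ± 0.14 (adjusted p = 0.00360) from a DMSO level below the array median, where RMA compresses folds. TXN (-0.14 ± 0.09), TKT (-0.083 ± 0.10) and PRDX1 (0.22 ± 0.09) were not called in either fit. Camera gave adjusted p = 1.66e-12 and 1.80e-17. With an estimated correlation the 6-array call was lost (adjusted p = 0.149 with an estimated correlation) and the 5-array call held (adjusted p = 0.0331).

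The androgen-induced genes, those that androgen raises in LNCaP cells, did not move one way. KLK3 had a log2 fold change of -0.14 ± 0.10 in the 5-array fit (adjusted p = 0.425), KLK2, a kallikrein neighbour of KLK3, -0.23 ± 0.14 (adjusted p = 0.351), and FKBP5, a cochaperone and androgen target, -0.21 ± 0.17 (adjusted p = 0.514). TMPRSS2, a membrane serine protease, fell by 0.70 ± 0.10 (adjusted p = 0.00136), a call made by 1 of its 2 probe sets. C1orf116 fell by 2.01 ± 0.11 (adjusted p = 1.82e-06) and SPDEF, an epithelial transcription factor, by 0.89 ± 0.11 (adjusted p = 3.59e-04), while TSC22D3, a leucine zipper gene also raised by glucocorticoids, rose by 1.99 ± 0.08 (adjusted p = 2.96e-07). Of 34 measured members, 6 rose and 6 fell in this fit (6 and 7 adjusted over the list alone), with a median of -0.049 (camera adjusted p = 0.915).

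In the 6-array fit, TSC22D3 was the 1 member called (1.82 ± 0.16, adjusted p = 0.0137; 1 higher and 0 lower adjusted over the list alone). The median there was 0.28, higher with gedunin (camera adjusted p = 0.0352; adjusted p = 0.660 with an estimated correlation), and without the array labelled DMSO 3 that direction turned. KLK3 had 1.97 ± 1.78 (adjusted p = 0.712), KLK2 0.43 ± 0.58 (adjusted p = 0.788), TMPRSS2 0.24 ± 0.81 (adjusted p = 0.917) and FKBP5 -0.31 ± 0.21 (adjusted p = 0.662), while C1orf116 had -0.83 ± 1.00 and SPDEF 0.065 ± 0.81, neither called. On the array labelled DMSO 3, KLK3 stood at 1.26% of its mean in DMSO 1 and 2.

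Of the genes that androgen lowers in LNCaP cells, some fell in the 5-array fit. Of 13 measured members, 0 rose and 6 fell (0 and 8 adjusted over the list alone), with a median of -0.26. The chemokine receptor gene ACKR3 fell by 0.85 ± 0.10 (adjusted p = 2.52e-04), the cholinesterase gene BCHE by 0.67 ± 0.09 (adjusted p = 8.50e-04), the opioid receptor gene OPRK1 by 0.55 ± 0.13 (adjusted p = 0.0150) and the imprinted gene PEG3 by 0.52 ± 0.09 (adjusted p = 0.00285). Camera gave adjusted p = 4.25e-04, lost with an estimated correlation (adjusted p = 0.153 with an estimated correlation). In the 6-array fit 0 members were called, also adjusted over the list alone (0 at an unadjusted p of 0.05), and the median was 0.59 (camera adjusted p = 0.286). The 4 genes named had the opposite sign there, at 0.70 (ACKR3), 0.59 (BCHE), 0.27 (OPRK1) and 1.26 (PEG3).

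Several transcription factors of luminal prostate cells fell in the 5-array fit. GATA2 fell by 1.24 ± 0.10 (adjusted p = 3.18e-05) and FOXA1, which opens chromatin at prostate enhancers, by 0.57 ± 0.11 (adjusted p = 0.00575). AMACR, a racemase used as a prostate cancer marker, fell by 1.17 ± 0.10 (adjusted p = 3.24e-05). Of the 11 measured members of the luminal prostate identity list, 2 rose, among them KRT18 (0.47 ± 0.09, adjusted p = 0.00590), and 5 fell (2 and 6 adjusted over the list alone). The median was -0.26 (camera adjusted p = 0.0525). With all 6 arrays, 0 members were called, also adjusted over the list alone (0 at an unadjusted p of 0.05), and the median was 1.39 (camera adjusted p = 0.193), while 7 of these genes lay at least 8-fold below the other 5 arrays on the array labelled DMSO 3. GATA2 had 0.24 ± 1.26, FOXA1 0.49 ± 0.90 and AMACR -0.18 ± 0.84 in that fit, the first 2 with the opposite sign.

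**Figure D3:**
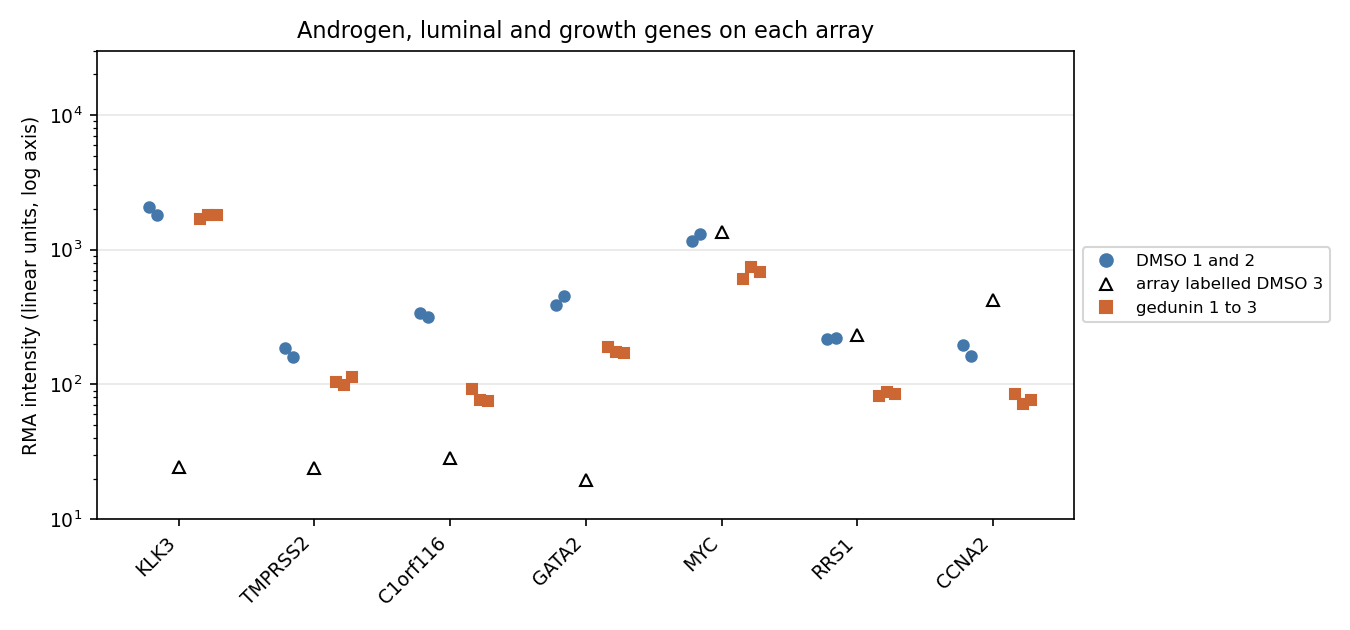
Intensity (linear units, logarithmic axis) of 4 androgen or luminal genes and 3 growth genes on each array, with 1 symbol per array. C1orf116, TMPRSS2 and GATA2 are lower on the 3 gedunin arrays than on DMSO 1 and 2 but lowest on the array labelled DMSO 3, KLK3 on DMSO 1 and 2 overlaps the gedunin arrays, and MYC and RRS1 are lower with gedunin than on all 3 DMSO arrays.

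Genes of ribosome biogenesis fell in part. In the 6-array fit, 3 of 23 measured members fell, RRS1, BYSL (-1.37 ± 0.20, adjusted p = 0.0471) and ODC1 (-0.81 ± 0.08, adjusted p = 0.0146), and 0 rose (6 lower and 0 higher adjusted over the list alone). BYSL is an assembly factor of the small ribosomal subunit and ODC1 the first enzyme of polyamine synthesis. Without the array labelled DMSO 3, 9 fell and 0 rose (12 and 0 adjusted over the list alone), among them NOP2, a ribosomal RNA methyltransferase (-0.90 ± 0.10, adjusted p = 1.84e-04). Medians were -0.43 and -0.27, with camera adjusted p = 9.09e-09 and 9.83e-05. Both calls were lost with an estimated correlation (adjusted p = 0.578 and 0.0851 with an estimated correlation). MYC, a transcription factor that drives many of these genes, fell by 0.91 ± 0.11 with all 6 arrays (adjusted p = 0.0330) and by 0.87 ± 0.11 without the array labelled DMSO 3 (adjusted p = 4.97e-04).

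DNA replication genes fell in part. In the 5-array fit, 9 of 23 measured members fell and 1 rose (12 and 2 adjusted over the list alone), with a median of -0.27. RRM2, a subunit of ribonucleotide reductase, fell by 1.30 ± 0.10 (adjusted p = 2.49e-05), the S-phase cyclins CCNE2 by 0.88 ± 0.13 (adjusted p = 0.00167) and CCNE1 by 0.83 ± 0.13 (adjusted p = 0.00168), while the origin licensing gene CDC6 rose by 0.98 ± 0.09 (adjusted p = 5.07e-05). Of 24 measured mitosis genes, 8 fell and 0 rose in that fit (10 lower and 1 higher adjusted over the list alone), with a median of -0.22. They included the cyclin gene CCNA2 (-1.20 ± 0.11, adjusted p = 6.45e-05), the motor gene KIF20A (-0.47 ± 0.12) and the kinase genes PLK1 (-0.44 ± 0.12) and AURKA (-0.48 ± 0.09, called by 1 of its 3 probe sets).

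With all 6 arrays, 0 genes of either list were called (7 in each at an unadjusted p of 0.05). Adjusted over the list alone there was 1 higher replication gene and no mitosis gene. The medians were -0.70 and -0.50, larger falls than without the array labelled DMSO 3 (-0.27 and -0.22). On that array RRM2 read 3379 and CCNA2 427, against means of 1016 and 178 on DMSO 1 and 2. Of the genes named from these lists, only CCNE2 read lower on it (51.7 against 70.8). How much of the fall with all 6 arrays came from that array was not tested. Camera gave adjusted p = 5.66e-05 and 4.25e-04 for replication in the 6- and 5-array fits and 2.66e-05 and 0.00388 for mitosis. All were lost with an estimated correlation (adjusted p = 0.579, 0.0977, 0.579 and 0.275 with an estimated correlation).

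Among the p53 targets, genes of growth arrest and cell death, CDKN1A, the cell cycle inhibitor p21, rose by 1.92 ± 0.12 (adjusted p = 0.00521) and GADD45A, a growth arrest gene, by 2.43 ± 0.19 (adjusted p = 0.00944) with all 6 arrays, where 2 of 17 measured members rose and 0 fell (7 and 0 adjusted over the list alone). In the 5-array fit, 11 rose and 1 fell (11 and 1 adjusted over the list alone), with CDKN1A (2.01 ± 0.10), GDF15, a stress cytokine (2.82 ± 0.09), and MDM2, the p53 ubiquitin ligase (2.01 ± 0.27), among the rises, and SESN1 (-0.65 ± 0.11; 0.81 with all 6 arrays) the fall. Only 1 of the 2 probe sets of GDF15 was called. Medians were 0.60 and 0.58, with camera adjusted p = 1.62e-04 and 2.20e-09, but without probe sets with the suffixes _x_at and _s_at the 6-array median was -0.0013 and the 5-array median 0.20. The 6-array call was lost with an estimated correlation (adjusted p = 0.180 with an estimated correlation), and the 5-array call held (adjusted p = 0.0459).

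In the autophagy and lysosome list, MAP1LC3B, an autophagosome membrane protein, rose by 1.31 ± 0.09 (adjusted p = 0.00647) and was the 1 of 23 measured members called with all 6 arrays (4 adjusted over the list alone, all higher). In the 5-array fit, 7 rose and 0 fell (8 and 0 adjusted over the list alone), among them the cargo receptor SQSTM1 (1.99 ± 0.10), GABARAPL1 (1.44 ± 0.13) and the initiating kinase ULK1 (0.68 ± 0.10), while the cathepsins CTSB (-0.24 ± 0.10) and CTSD (0.29 ± 0.13) were not called. A dimmer probe set of CTSB was called lower (-0.45, limma adjusted p = 0.0272). Medians were 0.39 and 0.16, with camera adjusted p = 5.66e-05 and 8.76e-04, lost with an estimated correlation (adjusted p = 0.578 and 0.165 with an estimated correlation).

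In the hypoxia and glycolysis list, the collagen prolyl hydroxylase P4HA1 (1.44 ± 0.09, adjusted p = 0.00538) and the histone demethylase KDM3A (1.49 ± 0.15, adjusted p = 0.0175) were the 2 of 21 measured members that rose with all 6 arrays (4 adjusted over the list alone), and 0 fell. The 5-array fit called 5 higher and 0 lower, the same numbers as adjusted over the list alone, adding P4HA2 (2.76 ± 0.11), the angiogenic factor VEGFA (2.19 ± 0.10) and ADM (0.69 ± 0.18). The glycolytic genes of this list were not among them, with LDHA at -0.24 ± 0.09, PGK1 at 0.026 ± 0.09 and SLC2A1 at -0.10 ± 0.10. The median was 0.31 (camera adjusted p = 0.00909) and 0.060 (camera adjusted p = 0.00371), lost with an estimated correlation (adjusted p = 0.180 and 0.193 with an estimated correlation). Centred on GAPDH and ACTB, the 5-array median was -0.071.

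Immediate early genes, which respond to signals without new protein synthesis, gave 2 rises of 27 measured with all 6 arrays, ATF3 and the transcription factor KLF4 (1.81 ± 0.18, adjusted p = 0.0188, from a DMSO level below the array median), and 1 fall, MYC, also adjusted over the list alone. The 5-array fit gave 9 rises, among them ZFP36, which destabilises AU-rich mRNAs (1.73 ± 0.14), and 1 fall, also adjusted over the list alone. FOS (0.21 ± 0.12) and EGR1 (0.11 ± 0.10) were not called and lay below the array median on DMSO 1 and 2. The medians were -0.0045 (mean 0.24 and camera direction up, camera adjusted p = 0.344) and 0.16 (camera adjusted p = 3.24e-04, lost at adjusted p = 0.153 with an estimated correlation). The latter was -0.0080 without probe sets with the suffixes _x_at and _s_at.

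The metallothionein and zinc export list had 1 rise of 8 measured genes in each fit, also adjusted over the list alone. It was the zinc exporter SLC30A1 (0.83 ± 0.11, adjusted p = 0.0364), while the metallothioneins, whose near-identical copies share probes, were not called. Its camera adjusted p was 0.0499 with all 6 arrays (adjusted p = 0.660 with an estimated correlation) and 0.602 without the array labelled DMSO 3, with medians of 0.48 and 0.030. Among 6 measured aryl hydrocarbon receptor targets, 0 were called with all 6 arrays, also adjusted over the list alone (1 at an unadjusted p of 0.05), and 2 rose and 2 fell in the 5-array fit (2 and 3 adjusted over the list alone). NQO1 rose by 1.20 ± 0.09 and TIPARP by 0.48 ± 0.09, while CYP1A1, a xenobiotic-metabolising cytochrome, fell by 1.57 ± 0.10 and CYP1A2 by 0.34 ± 0.10. That list had medians of -0.14 and -0.17 and camera adjusted p = 0.680 and 0.846.

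The metabolic lists moved little. Of 26 measured oxidative phosphorylation genes, 0 were called with all 6 arrays (2 at an unadjusted p of 0.05) and 1, ATP5MC3, a subunit of ATP synthase, fell in the 5-array fit, by 0.32 ± 0.09 (0 adjusted over the list alone in each fit). The median was -0.054 (camera adjusted p = 0.184) and -0.12 (camera adjusted p = 0.0145, lost at adjusted p = 0.340 with an estimated correlation). Of 17 measured cholesterol synthesis genes, 0 were called with all 6 arrays (2 at an unadjusted p of 0.05), and SC5D (0.64 ± 0.09) rose and NSDHL (-0.64 ± 0.11) fell in the 5-array fit, as adjusted over the list alone. HMGCS1, an early enzyme of the pathway, had 0.16 ± 0.15 (adjusted p = 0.713) and 0.27 ± 0.11 (adjusted p = 0.144). This list had medians of -0.23 and -0.071 and camera adjusted p = 0.114 and 0.602. Of 10 measured fatty acid synthesis genes, 0 were called with all 6 arrays (0 at an unadjusted p of 0.05) and 1, the elongase ELOVL6 (-0.37 ± 0.11; 0.064 with all 6 arrays), fell in the 5-array fit (0 adjusted over the list alone), with medians of 0.074 and -0.068 and camera adjusted p = 0.356 and 0.602.

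Of 28 measured proteasome subunit genes, 0 were called with all 6 arrays (3 at an unadjusted p of 0.05) and 2, PSMD12 (0.35 ± 0.10) and PSMA3 (0.31 ± 0.09), rose in the 5-array fit (0 adjusted over the list alone in each fit). The median was 0.16 with all 6 arrays (camera adjusted p = 0.0311; adjusted p = 0.579 with an estimated correlation) and 0.033 without the array labelled DMSO 3 (camera adjusted p = 0.143). Of 8 measured replication-type histone genes, 0 were called with all 6 arrays (1 lower adjusted over the list alone, 1 at an unadjusted p of 0.05), and H4C8 (0.50 ± 0.12) rose and H2BC8 (-0.81 ± 0.08), H1-2 (-0.58 ± 0.12) and H2BC5 (-0.36 ± 0.09) fell in the 5-array fit, the same counts as adjusted over the list alone. Their medians were 0.18 and -0.17, with camera adjusted p = 0.973 and 0.106.

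The immune signalling lists depended on the array labelled DMSO 3. Of 17 measured NF-kB targets, 0 were called with all 6 arrays (2 at an unadjusted p of 0.05) and the median was -0.64 (camera adjusted p = 0.0311; adjusted p = 0.729 with an estimated correlation). The 5-array fit gave a median of -0.042 (camera adjusted p = 0.602), with 0 rises and 2 falls, the inhibitor gene NFKBIA (-0.75 ± 0.12) and NFKB1 (-0.80 ± 0.10), also adjusted over the list alone. Of 19 measured interferon response genes, 0 were called with all 6 arrays (0 at an unadjusted p of 0.05) and the median was -0.91 (camera adjusted p = 0.00424; adjusted p = 0.729 with an estimated correlation). The 5-array fit gave -0.060 (camera adjusted p = 0.828), with BST2 (0.39 ± 0.09) and IFIH1 (0.39 ± 0.11) higher and IRF9 (-0.40 ± 0.10), ISG15 (-0.37 ± 0.11) and IFI6 (-0.35 ± 0.10) lower, also adjusted over the list alone. BST2 and IFIH1 lay below the array median on DMSO 1 and 2 but read 857 and 96.2 on the array labelled DMSO 3, and with all 6 arrays they had the opposite sign, at -1.49 and -0.38.

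The lists of other cell types had 0 called members with all 6 arrays, also adjusted over the list alone, and at an unadjusted p of 0.05 they had 0 (leukocytes), 1 (stromal), 3 (basal and mesenchymal) and 0 (neuroendocrine). Their medians there were -1.29 for leukocytes (10 measured, camera adjusted p = 0.250), -0.037 for stromal cells (12 measured, 0.848), -0.026 for basal and mesenchymal prostate lines (10 measured, 0.973) and 0.16 for neuroendocrine genes (9 measured, 0.184). Their medians in the 5-array fit were 0.028, 0.077, 0.088 and 0.070, with camera adjusted p = 0.923, 0.0924, 0.803 and 0.923. The camera direction in the 6-array fit was up for the stromal list, whose mean was 0.073, and for the basal and mesenchymal list, whose mean was -0.26. It was down in the 5-array fit for the neuroendocrine list (mean -0.033) and up for leukocytes (mean -0.0077). No leukocyte gene was called in that fit (1 at an unadjusted p of 0.05), ACTA2 (0.76 ± 0.09; -0.22 with all 6 arrays) and COL1A1 (0.75 ± 0.10) of the stromal list rose (3 higher adjusted over the list alone), VIM, an intermediate filament of mesenchymal cells (-0.52 ± 0.09), fell, and the neuropeptide gene NTS (-0.47 ± 0.09; 1.26 with all 6 arrays) fell, both also adjusted over the list alone. The other probe sets of ACTA2 and COL1A1 were not called.

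**Figure D4:**
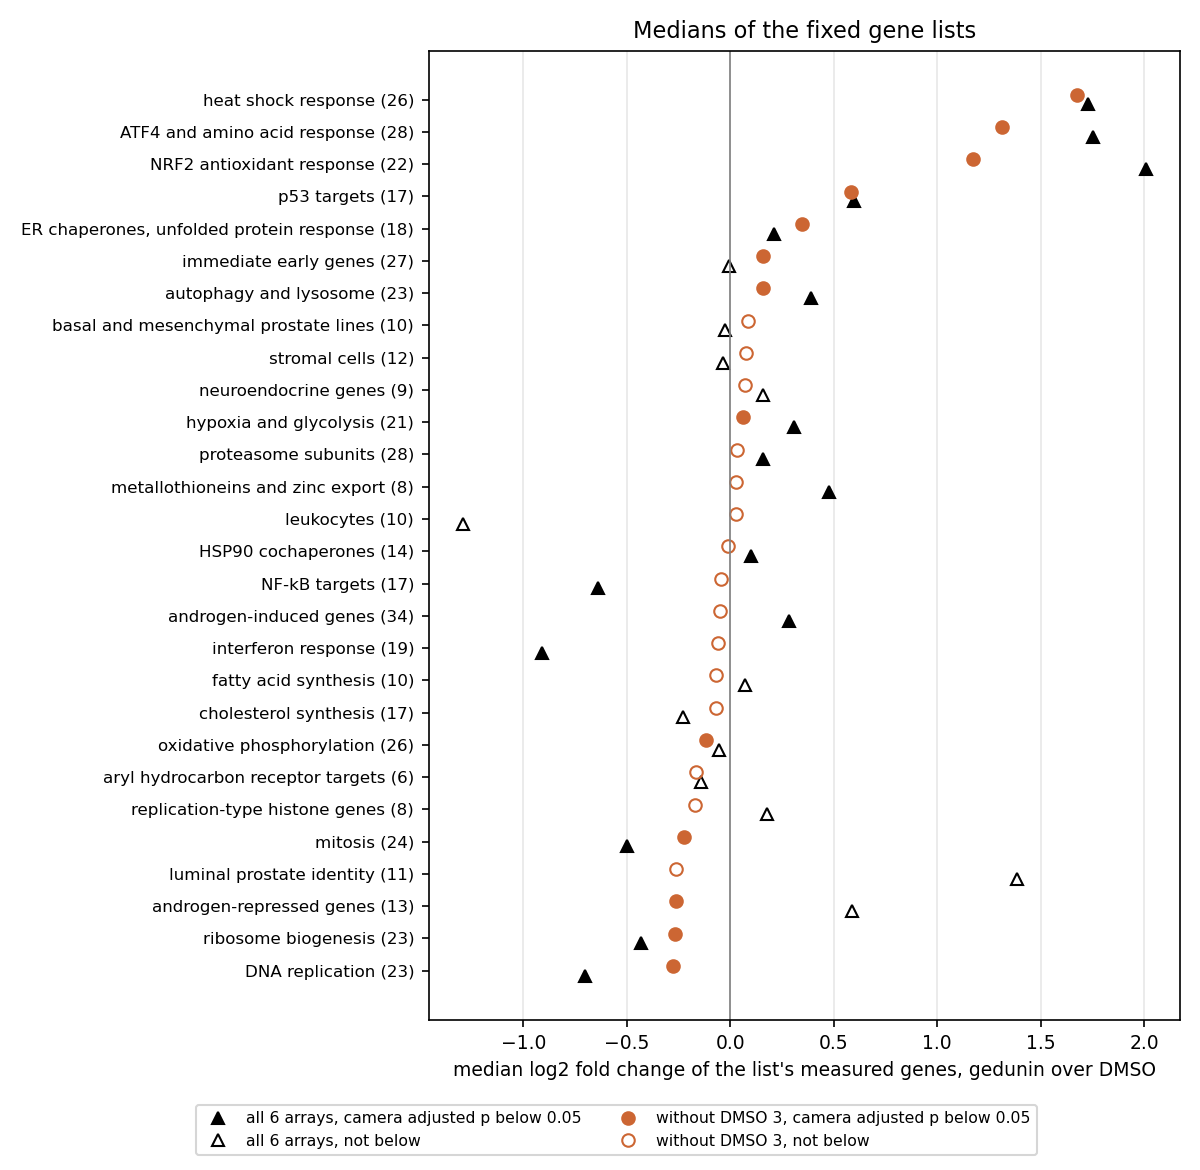
Median log2 fold change, gedunin over DMSO, of the measured genes of each of the 28 fixed lists (number of genes in brackets), for all 6 arrays (triangles) and without the array labelled DMSO 3 (circles). Filled symbols have a camera adjusted p below 0.05 at the preset correlation, and the luminal, leukocyte, interferon and androgen-repressed medians lie nearer 0 without that array.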

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

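Signal from genes of other cells was found on the array labelled DMSO 3. The predictions for the lineage lists were written before those tests were run, and those for a mixture, failed hybridisation, a swap, the origin of the calls, scaling and the androgen direction after the result was seen. The median log2 difference from DMSO 1 and 2 was 3.55 over 10 leukocyte genes and 3.76 over 9 measured B lymphoid genes. Compared with the mean of the other 5 arrays, 6 of 9 epithelial genes and 2 of 9 neuroendocrine genes lay at least 8-fold below, 2 of 10 basal and mesenchymal genes (CD44 and VIM) lay at least 8-fold above, and 0 of 12 stromal genes lay outside these limits.

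The signal might come from a sample of B lymphoid cells under this label, a hypothesis for which 6 of 9 B lymphoid genes lay at least 8-fold above the mean of the other 5 arrays. Folds over that mean included 134 for POU2AF1 (intensity 2393), 86.1 for MS4A1 (2138), 22.6 for CD79A (515) and 18.6 for BLNK (782). The genes that missed this limit were CD72 (3.11-fold), PAX5 (1.23-fold) and VPREB1 (1.15-fold). Of the 9 genes, 1 lay above the array median on the other 5 arrays and 1 is also on the leukocyte list. The counts were 1 of 9 for a sample of T lymphoid cells (LCK, 28.8-fold, intensity 572), 0 of 9 for myeloid cells and 0 of 9 for erythroid cells. LNCaP cells mixed with other cells would likely keep more FOLH1 than the 0.338% of its mean in DMSO 1 and 2 seen here, and degraded RNA or a failed hybridisation would likely not put 669 probe sets at least 4-fold above every other array. A swap with a gedunin array of this series might leave a gedunin array out of place, but the lowest median Spearman correlation of a gedunin array with the 4 arrays besides itself and that array was 0.971, and which sample was hybridised cannot be settled from these data.

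The rise of stress response genes might have been made by the array labelled DMSO 3. Without it, 25 of 26 measured heat shock genes were still called higher, with a median of 1.68, so that array was not needed for their rise. In addition, 100% of the genes called with all 6 arrays passed in the same direction without that array. That share tests little, because genes on which that array differs have a wide spread in DMSO and are seldom called with all 6 arrays. Scaling between arrays might also have produced the rise. After a second quantile normalization the heat shock median lay 1.67 above the median of all genes with all 6 arrays and 1.63 without the array labelled DMSO 3. RMA had already applied quantile normalization, so a second pass could change little and cannot settle this. Centring shifts all genes of an array alike, so it cannot change the difference between the heat shock median and that of all genes, and tests nothing here.

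For the higher androgen-induced and luminal lists with all 6 arrays, the array labelled DMSO 3 likely set the direction, since the higher of the 2 medians without it was -0.049.

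The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The grouping by gedunin gave 312 probe sets, 204 genes and 124 genes with 2-fold changes, with 0 as the highest of the other splits for each, so that 1 of the 10 splits gave as many of each. The heat shock median was 1.73 against a highest other of 0.61 (1 of 10 splits as large), the androgen-induced median 0.28 against 0.42 (10 of 10), and the count of other lists past the threshold 14 against 17 (4 of 10). The splits of the 5 arrays into 3 and 2 are also 10 and too few, with 3396 probe sets against 0 (1 of 10).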

How the results depend on the processing

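The settings were planned before the data were seen, including leaving out each array in turn. Centring on GAPDH and ACTB was chosen after seeing the data. So were the use of the fit without the array labelled DMSO 3 throughout and every further setting run without that array. The heat shock response list kept its direction and passed under every setting run, with medians of 1.65 to 2.30 with all 6 arrays and 1.55 to 2.15 without the array labelled DMSO 3. Where a value changed and no cause is stated, the cause was not tested.

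With all 6 arrays, the counts of 312 probe sets, 204 genes and 124 genes with 2-fold changes became 96, 70 and 68 when centred on GAPDH and ACTB, and 2703, 1703 and 298 with array weights, where the array labelled DMSO 3 had a weight of 0.0605 and the others 1.40 to 2.37. Without probe sets with the suffixes _x_at and _s_at, where fewer probe sets were tested, 95 probe sets were higher and 21 lower (1.2e+02 after rounding), and 94 genes and 64 genes with 2-fold changes passed. With trend and robust, 169 probe sets and 112 genes passed, and 57 probe sets passed the stricter threshold of 0.01. Leaving out each array gave 7 to 3396 probe sets, 6 to 2138 genes and 6 to 296 genes with 2-fold changes, with the highest values without the array labelled DMSO 3 and fewer calls than with all 6 arrays without any other array. The 14 other lists past camera became 8 without those suffixes, 5 with fry and 0 with an estimated correlation.

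Arrays of the 2 groups share replicate numbers, and whether these pair the arrays is not stated. Deviations from the group means, computed without the array labelled DMSO 3, correlated by -0.033 and 0.039 for the numbers 1 and 2, so no pairing was seen, although 2 DMSO arrays mirror each other around their mean and test this weakly. With a replicate block, which costs degrees of freedom, limma called 2 probe sets, 1 gene and 1 gene with a 2-fold change with all 6 arrays. Without the array labelled DMSO 3 it called 2931 probe sets, 1850 genes and 312 genes with 2-fold changes. In that blocked fit gedunin 3 is alone in its block, so only the arrays numbered 1 and 2 inform the comparison.

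Without that array, 3396 probe sets and 2138 genes became 5269 and 3272 when centred on GAPDH and ACTB. They became 1586 and 1274, and the 296 genes with 2-fold changes 170, without the suffixes _x_at and _s_at, and 1869 probe sets passed the threshold of 0.01. Leaving out a further array gave 1805 to 3064 probe sets and 1152 to 1935 genes. Where this left a single DMSO array, that array was assumed to vary like the gedunin arrays. The 12 other lists past camera became 3 with an estimated correlation. With fry, which does not set a list against other genes, the lists lost that way passed. Its adjusted p was 4.68e-04 (ER), 0.00190 (hypoxia), 6.09e-04 (ribosome biogenesis), 0.00253 (autophagy), 0.00518 (androgen-repressed) and 0.00571 (immediate early). For replication it was 0.00200, and for mitosis and oxidative phosphorylation 0.0196. Lists not called by camera also passed fry, namely luminal (0.00518), NF-kB (0.0196), histones (0.0196), stromal (0.0196) and fatty acid synthesis (0.0443). The HSP90 cochaperones (0.0575) did not.

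The androgen-induced median of 0.28 was 0.40 with a filter on dim probe sets, 0.31 when centred on array medians, 0.073 without the suffixes, 0.15 with the mean of all probe sets and 0.28 with an estimated correlation or fry, each no longer past the threshold. It was -0.011 with array weights and -0.049 to 0.53 when each array was left out. Without the array labelled DMSO 3 it was -0.091 to 0.0077 when a further array was left out.

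With array weights, other medians with all 6 arrays turned to -0.0094 (HSP90 cochaperones), -0.18 (androgen-repressed), 0.10 (immediate early), -0.043 (fatty acid synthesis), -0.13 (histones), -0.13 (luminal), 0.089 (basal and mesenchymal) and 0.075 (stromal). Leaving out each array gave -0.0096 to 0.22, -0.26 to 1.21, -0.11 to 0.16, -0.068 to 0.26, -0.17 to 0.35, -0.26 to 2.31, -0.050 to 0.088 and -0.094 to 0.077 for these lists in the same order, and -1.89 to 0.028 for leukocytes. Without the suffixes the p53 median was -0.0013, the histone median -0.12 and the basal and mesenchymal median 0.063. The immediate early median was 0.030 with the filter, 0.019 when centred on array medians and 0.021 with the mean of all probe sets.

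Among genes with all 6 arrays, TMPRSS2 turned to -0.70 with array weights (-0.70 to 0.77 leaving out each array), KLK3 to -0.061 (-0.14 to 3.07) and KLK2 to -0.16 (-0.23 to 0.81), while HMGCS1 turned to -0.34 with the mean of all probe sets. In the 5-array fit, AURKA turned to 0.31 without the suffixes, where another probe set stood for it, and FKBP5 to 0.0013 with a replicate block (-0.34 to 0.0013 leaving out each array).

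List medians near 0 also changed sign without the array labelled DMSO 3. Centred on GAPDH and ACTB, which lowers every value alike, they were -0.10 (metallothioneins), -0.071 (hypoxia), -0.098 (proteasome), -0.043 (basal and mesenchymal), -0.054 (stromal), -0.10 (leukocytes) and -0.061 (neuroendocrine). Without the suffixes they were 0.050 (HSP90 cochaperones), -0.0080 (immediate early), -0.080 (stromal) and -0.037 (leukocytes). With the filter they were 0.073 (aryl hydrocarbon receptor targets) and -0.24 (neuroendocrine), and the proteasome median was -0.013 after a second quantile normalization. The HSP90 cochaperone median was 0.011 when centred on array medians, 0.0049 with a replicate block and 0.032 with the mean of all probe sets. Leaving out a further array gave -0.050 to 0.026 (HSP90 cochaperones), -0.0078 to 0.054 (metallothioneins), -0.084 to 0.013 (interferon) and -0.027 to 0.049 (leukocytes).

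Over all settings, named genes kept direction and side of the threshold 535 times, lost the call 263 times, gained it 8 times and changed sign 7 times with all 6 arrays, and 1455, 66, 2 and 3 times without the array labelled DMSO 3. Centring on AFFX controls was not run, because the table holds none. Near background, where many probe sets lie, RMA compresses folds.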

Other observations

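Genes outside the fixed lists are described here for the 5-array fit and were chosen after their values were seen. The paralogous epithelial splicing regulators moved in opposite directions, with ESRP1 at 2.03 ± 0.10 (adjusted p = 6.01e-07) and ESRP2 at -1.42 ± 0.14 (adjusted p = 1.23e-04). The transcription factor genes GRHL2 (-1.03 ± 0.10) and OVOL2 (-1.04 ± 0.09), both of epithelial cells, and the receptor tyrosine kinase gene ERBB2 (-0.82 ± 0.09) fell. The relaxin genes RLN1 (-1.08 ± 0.10) and RLN2 (-1.55 ± 0.12) fell, and their sequences are similar enough that probe sets may share signal. ZBTB16 (-1.33 ± 0.11) and KLF9 (-1.12 ± 0.16), known targets of steroid hormone receptors, fell while TSC22D3, another such target and a member of the androgen-induced list, rose (1.99 ± 0.08). Large rises included the calcium-binding protein gene S100P (2.90 ± 0.10), the calcitonin gene CALCA (2.80 ± 0.11), the apoptosis gene PMAIP1 (2.59 ± 0.09), the secreted chaperone gene CLU (2.02 ± 0.14) and FICD (2.39 ± 0.10), which modifies the ER chaperone BiP. With all 6 arrays, S100P (3.06 ± 0.17, adjusted p = 0.00360), CALCA (2.79 ± 0.11, adjusted p = 0.00195) and FICD (2.31 ± 0.11, adjusted p = 0.00333) also rose, CALCA from a DMSO level below the array median, where RMA compresses folds. The other genes of this paragraph besides TSC22D3 were not called with all 6 arrays, and GRHL2 (0.10), ERBB2 (0.84) and RLN1 (0.42) had the opposite sign.

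Among 154 families of genes sharing the letters before the first digit of their symbol, an alternative added after seeing the data, limma's camera called 3 at an adjusted p of 0.05 in the 5-array fit, the only fit in which families were tested. The HSPA family (13 genes) had a median of 1.08 with 11 higher and 0 lower (adjusted p = 1.02e-13; adjusted p = 0.516 with an estimated correlation). Most of its members, HSPA6 and HSPA1A among them, are also on the heat shock list, so this call largely repeats that result. Called members on none of the fixed lists were HSPA13 (2.27 ± 0.09), HSPA9 (0.68 ± 0.09) and HSPA14 (0.45 ± 0.10). The PIK family (12 genes), mostly catalytic and regulatory subunits of phosphoinositide 3-kinases, had a median of -0.68 with 7 lower and 0 higher, among them PIK3R3 (-1.11 ± 0.09) and PIK3CB (-0.83 ± 0.10). The POLR family (26 genes), mostly RNA polymerase subunits, had a median of -0.23 with 10 lower and 0 higher, among them POLR1C (-1.41 ± 0.10). For both the PIK and the POLR family adjusted p = 0.0173, or adjusted p = 0.962 with an estimated correlation. The INTS family (12 genes), subunits of the Integrator complex, had a median of -0.30 with 5 lower and was not called (adjusted p = 0.155).

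The higher p53 targets of the 5-array fit could reflect 5 members picked from general knowledge as also responding to other stress, none of which is on another fixed list. The predictions for this test were written before it was run, and the 5 genes were chosen after seeing the data. Without GDF15, GADD45A, BBC3, CDKN1A and PLK3, the 12 remaining genes had a median of 0.41 in the 5-array fit, with 7 higher and 1 lower, so these 5 may not account for all of it.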
